A study of Mus musculus with 14 samples.

How the data were processed

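The study measured total RNA of HSCs from C57BL/6 bone marrow, sorted by calcium level into 2 groups of 7 libraries with 100 cells each. The labels describe first-strand synthesis with not-so-random primers, a second strand by Klenow fragment, Nextera XT libraries and sequencing on a NextSeq system. They name the sorted cells as HSCs and give no other sort gate. They do not say whether libraries come from separate animals, so p-values here measure only the spread between these samples.

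The deposited values are RPKM computed by the authors (reads per kilobase of gene model, scaled to the library total), given as one file per library. The submitters' processing notes name the builds GRCm38 and mm10 and the tool edgeR, with no role or version. The aligner, the counting tool and the annotation were not given in the sources used here. The header names no unit; RPKM was read from the values. In each gene the values of the 14 libraries were whole multiples of a common step, so whole reads could be recovered. All of 9848 genes above 0 in all libraries with a mean of 1 RPKM or more resolved to within 0.02 reads, against 2 of 500 genes whose values had been jittered. The step times gene length gave one constant for 122 of 581 short genes, which set the scale of the reads. The library totals the authors divided by were 14.3 to 37.2 M reads, and the listed genes held 25.0% to 32.5% of them.

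Each file listed 48737 gene labels. Of these, 23 had been turned into 5-digit serial numbers and were left out, and 48714 were joined across files, of which 18207 were above 0 in any library. The 13 protein-coding genes of the mitochondrial genome, Xist and Malat1 were listed at 0 in all libraries and were not tested. Of the labels, 4568 carry a copy suffix (1934 gene names, of which 215 have 2 or more copies at a mean of 1 RPKM or more); which annotated copy a suffix marks is not given, so such labels are reported as listed. Coordinates are those of the GRCm38 annotation.

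The design had assumed read counts and a test for counts. Because the deposited unit was RPKM, for which the design set a fallback, edgeR and DESeq2 were not used. The recovered reads would have allowed fits on counts, and of these only limma-voom was run. The fallback fixed with the design was limma (version 3.58.1, R 4.3.3) with a mean-variance trend on log2(RPKM + 1). It tested 9921 genes with a mean of 1 RPKM or more, calcium-high minus calcium-low, at a Benjamini-Hochberg adjusted p under 0.05. A pseudocount of 1 shrinks the fold changes of genes at low RPKM. Tables were read and summarised with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9. Gene lists, 37 in all, were fixed before the data were examined. They were tested with camera of limma, which asks whether the genes of a list lie higher or lower than all other genes, with a preset correlation of 0.01, and 29 had the required 5 tested members. The design also planned fry of limma, a list test that does not compare with other genes, and it was run beside camera. Lists with fewer tested members were the mitochondrially encoded genes (0), B and plasma cells (1), T, NK and innate lymphoid cells (4), mast cells and basophils (2), stromal and osteolineage cells (2), sex-linked genes (4), small noncoding RNA (0) and nuclear-retained long noncoding RNA (0). Their tested members had 0 calls over all genes, with or without the block. Whole-library measures were compared by exact two-sided permutation.

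The design set replicates 1 to 3 and 4 to 7 apart as library sets because of the order in which the samples are listed. The labels do not state separate preparations. The sets also differed in depth (3.58 to 7.39 and 8.28 to 10.3 M reads in listed genes). Between libraries of a group the variance was 3.62 to 59.4 times the counting variance over genes with a mean of 50 reads or more, and 3.62 to 20.5 times within a library set. Other sources of that spread were not separated. Libraries with the same number were compared for pairing before the fits were: the deviations of their genes from the group means were correlated at 0.384 to 0.715 in all 7 pairs, which met the rule that every pair exceed 0.1. Within a library set the correlations were -0.0647 to 0.552, and 5 of 14 libraries had their own number as the best partner. Replicates 1 and 2 of both groups held 1298 to 1638 reads of Y-linked genes and the other replicates 0 to 4. Fits with and without the replicate number as a block are therefore both given.

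Alternatives were other scalings (median of ratios, upper quartile), limma-voom with library quality weights on the recovered reads, no filter, a filter of 5 CPM in 7 libraries, pseudocounts of 0.1 and 5, the replicate block, the library set as a term, each set alone, genes detected as a covariate, an estimated correlation in camera, and leaving out each library in turn. Chosen after the data were seen were the block together with another scaling, voom, an estimated correlation or 1 pair left out, the sets alone with another scaling, and both libraries of replicate 3 left out.

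Genes were named by a rule. Its parts were the 10 called genes with the smallest p in each direction with a mean of 5 CPM or more (with fewer than 5 calls, the 5 genes with the smallest p, said not to pass), the 2 to 4 members with the smallest p in each described list, and a panel of HSC, cell cycle and progenitor genes. Genes named for other reasons are marked in the text.

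The tests were checked on simulated data made from 9835 genes with seeded changes. At a log2 change of 1 the fit of 14 libraries recovered 76 of 99 seeded genes without the block and 85 with it, replicates 4 to 7 alone 73, replicates 1 to 3 alone 38, and limma-voom 81. At a log2 change of 2 they recovered 99, 100, 98, 91 and 99 of 100. Unseeded calls were 1, 5, 11, 16 and 2, no seeded gene was called in the wrong direction, and camera called 0 of 20 null lists and the shifted list in each comparison. The simulated genes were drawn independently, while the estimated correlation was 0.508 for S phase and 0.877 for G2 and M phase genes. The check therefore cannot show how often camera calls lists of correlated genes falsely. It also held no variation shared within pairs, so it did not test the pairing.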

Results

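RNA was sequenced from haematopoietic stem cells (HSCs), the bone marrow cells from which the blood lineages arise, of C57BL/6 mice. The HSCs were sorted into a population with high calcium, [Ca2+]high (calcium-high), and one with low calcium, [Ca2+]low (calcium-low). Each group had 7 libraries numbered 1 to 7, each made from 100 sorted cells. The listed genes held 3575282 to 7388354 reads per library in replicates 1 to 3 and 8280756 to 10296314 in replicates 4 to 7. A gene of 1 kilobase listed at 0 could have had up to 0.0808 to 0.210 RPKM, depending on the library (3 reads, counting error only). The title of the series asks how dormant HSCs differ from active HSCs and names cytoplasmic calcium as a regulator of dormancy. The comparison of calcium-high with calcium-low HSCs asks which transcripts go with the calcium level.

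Calcium-high HSCs had more transcript of Vwf, the platelet adhesion protein von Willebrand factor that marks platelet-biased HSCs, and of the HSC surface receptor Slamf1 (CD150). They had less of Cd34 and Flt3, which rise as long-term HSCs become multipotent progenitors, and of Cdk6, a kinase that acts in the entry into the cell cycle. These differences passed by limma on log2(RPKM + 1) with the replicate number as a block and not without it. Vwf (GRCm38 chromosome 6, 125546774 to 125686679) was at 17.3 ± 5.88 RPKM in calcium-high and 4.87 ± 2.44 RPKM in calcium-low libraries (SD, n = 7; limma adjusted p = 0.0337 with the replicate number as a block), higher in all 7 pairs of libraries with the same number. Cd34 (chromosome 1, 194938819 to 194961279) was at 22.6 ± 6.84 against 45 ± 12.8 RPKM (adjusted p = 0.0272, limma with the block), lower in all 7 pairs. Flt3 (chromosome 5, 147330741 to 147400489) was at 1.73 ± 0.744 against 5.01 ± 2.15 RPKM (adjusted p = 0.0364, limma with the block), lower in 6 of 7 pairs. Without the block the limma adjusted p was 0.0504 for Vwf, 0.244 for Slamf1, 0.138 for Cd34, 0.152 for Flt3 and 0.150 for Cdk6. In replicates 1 to 3 alone the directions were the same, with a limma adjusted p of 0.421 for each gene.

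The number of genes called differed between fits and with the libraries included. With the replicate number as a block, limma called 48 genes higher and 43 lower in calcium-high HSCs among 9921 tested, with 1377 genes at an unadjusted p under 0.05. Without the block, limma called 0 genes in either direction, with 669 at an unadjusted p under 0.05. The smallest adjusted p was then 0.0504, shared by Vwf, Ehd3, Cd53 and Serpinb1a. On the recovered reads, limma-voom with library quality weights called 465 genes higher and 249 lower without the block. These included 88 of the 91 genes called with it. The library weights were 0.19 to 0.934 in replicates 1 to 3 and 0.813 to 2.61 in replicates 4 to 7. That fit therefore leaned on replicates 4 to 7, which alone also called 88 of the 91 by limma. Without the block and without both libraries of replicate 3, limma called 119 genes, and 101 without calcium-high replicate 3 alone. The count with the block was 8 without pair 1, 3 without pair 2, 302 without pair 3, 12 without pair 5 and 2 without pair 6. It was 0 without pair 4 or pair 7, with 1101 and 1108 genes at an unadjusted p under 0.05. All 91 genes kept their direction in each of these fits, with a median ratio of fold changes from 0.928 to 1.10. This was nearly fixed in advance, since the genes were chosen on all pairs and each fit reused the remaining pairs. Higher calls were 52.7% of all calls with the block and 75% (216 higher, 72 lower) with the block and median-of-ratios scaling.

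The 10 genes called higher with the smallest p in the paired fit covered several functions. Sult1a1, a sulfotransferase, was at 6.73 ± 2.76 against 2.27 ± 1.21 RPKM. Tns2, a focal adhesion protein, was at 4.78 ± 2.22 against 1.11 ± 0.598 RPKM. Tbxas1, thromboxane A synthase, was at 26.9 ± 5.06 against 16.7 ± 3.84 RPKM. Slamf1 was at 3.57 ± 0.728 against 2.03 ± 0.914 RPKM. The others were Vwf, Evc2 (a ciliary protein of hedgehog signalling), Rin2 (a guanine nucleotide exchange factor for Rab5), Nbea (neurobeachin) and Lhcgr (the luteinizing hormone receptor). The last of the 10 was Pygm_2 (muscle glycogen phosphorylase, a label with a copy suffix). The log2 fold changes of the 10 ran from 0.60 for Rin2 to 1.68 for Vwf, and their adjusted p with the block from 0.0272 to 0.0337. Each was higher in 7 of 7 pairs.

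Of the 10 genes called lower with the smallest p in the paired fit, Cd53, a tetraspanin of leukocytes (chromosome 3, 106759921 to 106790149), was at 1.58 ± 0.686 in calcium-high and 4.73 ± 1.49 RPKM in calcium-low libraries. It had the smallest adjusted p with the block, 0.0163. Cd69, an early activation antigen, was at 1.02 ± 1.10 against 3.58 ± 2.15 RPKM. Rgs1, a regulator of G-protein signalling, was at 22.6 ± 18.5 against 49.2 ± 10.7 RPKM. Rel, a subunit of NF-kB, was at 2.60 ± 0.763 against 4.44 ± 0.716 RPKM, and Tnfaip3, an inhibitor of NF-kB signalling, at 4.37 ± 2.14 against 7.52 ± 2.91 RPKM. The others were Cd34, Serpinb1a (an inhibitor of neutrophil serine proteases), Kcna3 (a voltage-gated potassium channel), Mdga1 and Dnajc6 (auxilin, which uncoats clathrin vesicles). Rgs1 was lower in 6 of 7 pairs and each of the other 9 in 7 of 7.

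**Figure D1:**
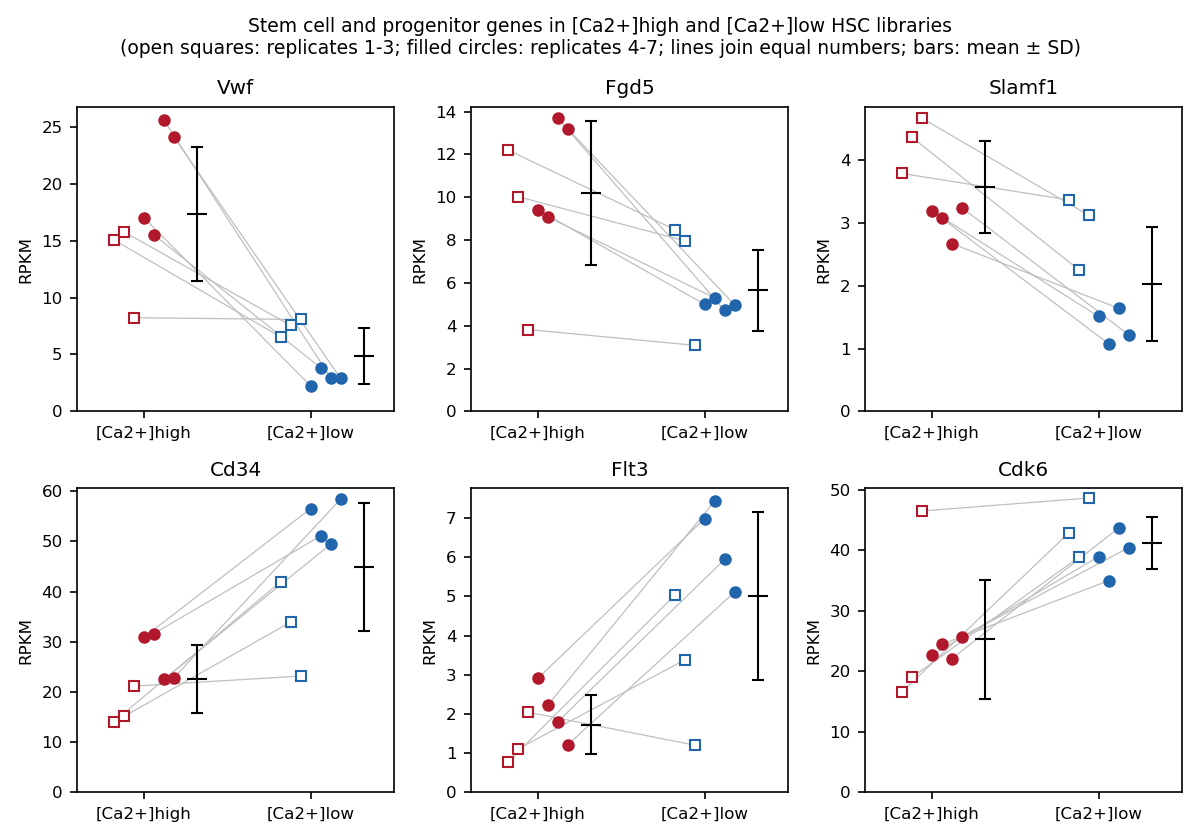
RPKM (vertical axis) of Vwf, Fgd5, Slamf1, Cd34, Flt3 and Cdk6 in the 7 calcium-high and 7 calcium-low libraries (horizontal axis), with open squares for replicates 1 to 3, filled circles for replicates 4 to 7, thin lines joining libraries of the same number, and bars for the mean ± SD. Vwf averaged 17.3 RPKM in calcium-high and 4.87 RPKM in calcium-low libraries, and Cd34 averaged 22.6 and 45 RPKM.

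Without the block the genes with the smallest p did not pass the threshold. In the higher direction they were Vwf, Ehd3 (an endocytic recycling protein), Ppp1r16b, Cyp26b1 (which degrades retinoic acid) and Amotl2. In the lower direction they were Cd53, Serpinb1a, Il1r1 (the interleukin 1 receptor), Runx3_1 (a label with a copy suffix) and Dnajc6. Their adjusted p ran from 0.0504 to 0.0990 without the block. With it they ran from 0.0163 to 0.0506, and Amotl2 was the gene above 0.05. Cyp26b1 was at 2.54 ± 1.28 against 0.502 ± 0.324 RPKM, and Ehd3 at 4.35 ± 1.06 against 1.76 ± 0.736 RPKM (SD, n = 7).

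Transcripts of long-term HSC identity were higher in calcium-high HSCs as a group, 24 of 29 tested members (camera adjusted p = 6.05e-09; adjusted p = 0.246 with an estimated correlation). Their median log2 fold change lay 0.28 above that of all tested genes, 0.19 above in replicates 1 to 3 and 0.30 above in replicates 4 to 7. With the block, 3 members passed over all genes, Fgd5, Procr and Slamf1, and 10 were higher and 0 lower when adjusted over the list alone. Without the block these counts were 0 over all genes and 6 higher, 0 lower adjusted over the list alone. Fgd5, a guanine nucleotide exchange factor that marks HSCs, was at 10.2 ± 3.36 against 5.65 ± 1.91 RPKM, and Procr (EPCR, an HSC surface marker) at 7.58 ± 2.55 against 4.24 ± 1.89 RPKM. Of the transcription factors, Hoxb5 was at 1.34 ± 0.343 against 0.705 ± 0.32 RPKM and Prdm16 at 4.22 ± 0.992 against 2.92 ± 0.487 RPKM. With the block, adjusted p was 0.175 and 0.115. Mecom (12.5 ± 2.76 against 8.45 ± 2.61 RPKM) and Hlf (46.3 ± 11 against 41.3 ± 8.67 RPKM) did not pass. Their adjusted p was 0.0711 and 0.685 with the block.

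Genes of HSC dormancy were higher, 16 of 24 members (camera adjusted p = 1.41e-05; adjusted p = 0.146 with an estimated correlation). The list median lay 0.17 above that of all tested genes in replicates 1 to 3 and 0.42 above in replicates 4 to 7. In replicates 4 to 7 alone the list did not pass (adjusted p = 0.195), and it passed there with median-of-ratios scaling (adjusted p = 0.0277). With the block 3 members were called higher, Cyp26b1, Sult1a1 and the retinoic acid receptor Rarb, and 1 lower, Zfp36 (tristetraprolin, which speeds the decay of messenger RNA). With it 11 were higher and 4 lower adjusted over the list alone. Without the block 0 passed over all genes and 7 higher, 0 lower adjusted over the list alone. Rarb was at 1.46 ± 0.534 against 0.636 ± 0.369 RPKM and Zfp36 at 42.8 ± 12.4 against 66.2 ± 24.1 RPKM. Both were named after their values were seen. Fhl1 (6.88 ± 1.49 against 3.91 ± 0.721 RPKM) and Nupr1 (2.52 ± 0.767 against 1.14 ± 0.812 RPKM) reached adjusted p of 0.0589 and 0.0544 with the block. Gprc5c, a retinoic acid-induced receptor of dormant HSCs, was at 0.324 ± 0.208 against 0.0380 ± 0.0457 RPKM, below the level needed for testing.

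Megakaryocyte and platelet genes were higher, 15 of 21 members (camera adjusted p = 3.38e-06; adjusted p = 0.146 with an estimated correlation). The list median lay 0.12 above that of all tested genes in replicates 1 to 3 and 0.28 above in replicates 4 to 7. The list mean itself was lower in calcium-high libraries in pair 1 (2.93 against 2.96 log2(RPKM + 1)) and pair 3 (3.06 against 3.23). The block gave Vwf and Clu (clusterin) higher and Plek (pleckstrin, a platelet signalling protein, named after its values were seen) lower over all genes. Adjusted over the list alone it gave 6 higher and 1 lower. Without the block 0 members passed over all genes and 4 higher, 0 lower adjusted over the list alone. Clu was at 4.16 ± 1.61 against 1.26 ± 1.17 RPKM, and Plek at 5.44 ± 5.28 against 8.26 ± 3.52 RPKM. Itgb3, the integrin subunit of the platelet fibrinogen receptor, was at 7.43 ± 1.81 against 4.43 ± 1.55 RPKM and Mylk, a myosin light chain kinase, at 1.87 ± 0.394 against 1.06 ± 0.430 RPKM. With the block, these had adjusted p of 0.0544 and 0.0859.

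Genes of multipotent progenitors were lower, 11 of 15 members (camera adjusted p = 0.00260; adjusted p = 0.70 with an estimated correlation). The list median lay 0.35 below that of all tested genes in replicates 4 to 7 and 0.19 below in replicates 1 to 3, where the list did not pass (adjusted p = 0.438) except with median-of-ratios scaling (adjusted p = 0.0245). The list mean was higher in calcium-high libraries in pair 5 (2.92 against 2.74 log2(RPKM + 1)) and pair 7 (2.74 against 2.57). With the block Cd34 and Flt3 passed over all genes, and 0 were higher and 6 lower adjusted over the list alone. Without it 0 passed over all genes and 0 higher, 3 lower adjusted over the list alone. Satb1, a chromatin organizer of lymphoid progenitors, was at 0.772 ± 0.0967 against 1.62 ± 0.670 RPKM, and Emb (embigin) at 3.91 ± 0.98 against 5.28 ± 1.2 RPKM. The adjusted p of these was 0.124 and 0.239 with the block. Cd48, a marker absent from long-term HSCs, was at 1.05 ± 0.904 against 1.54 ± 0.622 RPKM (adjusted p = 0.416 with the block). The fit with genes detected as a covariate ended the call (adjusted p = 0.188).

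Immediate early genes, which are transcribed within minutes of stimulation or tissue dissociation, were lower, 20 of 28 members (camera adjusted p = 4.94e-04; adjusted p = 0.146 with an estimated correlation). The sets of libraries differed. The list median lay 0.39 below that of all tested genes in replicates 4 to 7 (adjusted p = 5.75e-11) and 0.11 above it in replicates 1 to 3 (adjusted p = 0.0838). The camera test of that difference, at the preset correlation, gave an adjusted p of 1.81e-15. No estimated correlation was tried for it or for the differences between library sets given below. With the block Jun, Zfp36 and Zfp36l1 passed over all genes, and 1 was higher and 10 lower adjusted over the list alone. Without it 0 passed over all genes and 0 higher, 3 lower adjusted over the list alone. Jun, a subunit of AP-1, was at 49.5 ± 11.5 against 76.5 ± 3.59 RPKM and Zfp36l1 at 5.21 ± 1.28 against 7.58 ± 1.76 RPKM. Ier3_1 (8.24 ± 1.71 against 11.8 ± 1.35 RPKM, a label with a copy suffix) and Btg2 (17.8 ± 5.57 against 28.7 ± 9.40 RPKM) did not pass, nor did Egr1 (38.9 ± 5.86 against 31.3 ± 6.46 RPKM). Their adjusted p was 0.0772, 0.124 and 0.193 with the block. The list's call ended with genes detected as a covariate (adjusted p = 0.0924) and with the block without pair 6 (adjusted p = 0.0556).

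All 39 tested S phase genes were lower in calcium-high HSCs (camera adjusted p = 3.54e-13; adjusted p = 0.387 with an estimated correlation). In either fit 0 members passed over all genes, and adjusted over the list alone 0 passed without the block and 6 lower with it. The replicative helicase subunits Mcm7 (20.4 ± 4.70 against 29.2 ± 5.64 RPKM) and Mcm4 (15.1 ± 2.63 against 20.6 ± 3.87 RPKM) and the replication licensing regulator Dtl (10.6 ± 2.61 against 16.1 ± 3.67 RPKM) did not pass. Adjusted p with the block was 0.0859, 0.107 and 0.0589. The difference was larger in replicates 1 to 3, with a list median 0.55 below that of all tested genes, than in replicates 4 to 7, with 0.18 below (adjusted p of the difference = 0.00276).

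All 40 tested G2 and M phase genes were lower (camera adjusted p = 5.60e-08; adjusted p = 0.717 with an estimated correlation), as were 40 of 41 replication-dependent histone genes (adjusted p = 2.70e-04; adjusted p = 0.733 with an estimated correlation). In both lists 0 members passed over all genes or adjusted over the list alone, with or without the block. Calcium-low replicate 3 stood apart in both. The G2 and M phase genes averaged 4.37 log2(RPKM + 1) there and 1.51 to 2.0 in the other calcium-low libraries, and the histone genes 4.28 against 1.32 to 2.59. Leaving out that library ended both calls (adjusted p = 0.0608 and 0.763), and limma-voom ended that of the histones (0.183). Leaving out both libraries of replicate 3 ended the histone call (adjusted p = 0.570) and not that of the G2 and M phase genes (adjusted p = 0.0171). In replicates 4 to 7 alone neither list passed (adjusted p = 0.219 and 0.757), and the difference between the library sets had adjusted p of 0.0156 and 0.0169. Mki67, a marker of cycling cells, was at 1.96 ± 1.61 in calcium-high and 11.7 ± 25.3 RPKM in calcium-low libraries (adjusted p = 0.475 with the block). It was at 69.0 RPKM in calcium-low replicate 3 and at 0.911 to 5.27 RPKM in the other 6 calcium-low libraries. The mitotic genes Dlgap5, Smc4 and Ect2 and the histone genes Hist1h3e and Hist1h4c had adjusted p of 0.375, 0.284, 0.346, 0.235 and 0.267 with the block.

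The same library held transcripts of the neutrophil and erythroid lineages. S100a8 and S100a9, the calprotectin subunits of neutrophils, were at 392 and 223 RPKM in calcium-low replicate 3 and at 0 to 6.30 and 0 to 0.959 RPKM in the other 13 libraries. The granule protein Ngp was at 98.4 against 0 to 0.216 RPKM. Car1, an erythroid carbonic anhydrase, was at 120 RPKM there, at 62.5 RPKM in calcium-high replicate 3, and at a median of 0.517 RPKM in the other 12 libraries. These genes were named after their values were seen.

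**Figure D2:**
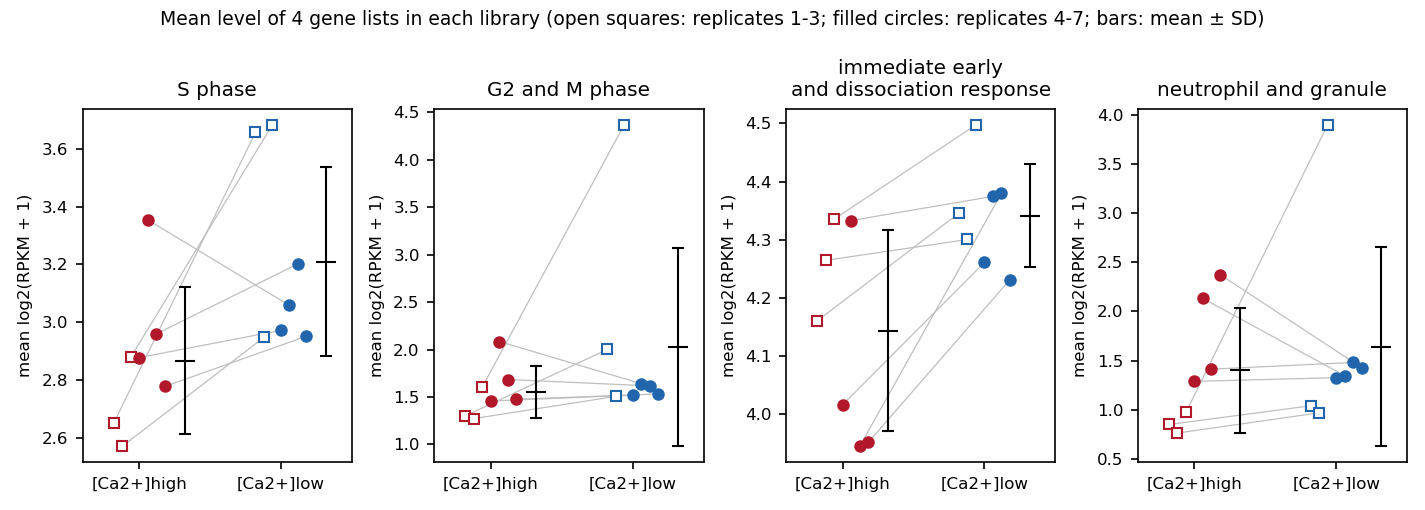
Mean log2(RPKM + 1) (vertical axis) of the S phase, G2 and M phase, immediate early and neutrophil lists in the 7 calcium-high and 7 calcium-low libraries (horizontal axis), with open squares for replicates 1 to 3, filled circles for replicates 4 to 7, thin lines joining libraries of the same number, and bars for the mean ± SD. Calcium-low replicate 3 had the highest mean of the G2 and M phase list (4.37) and of the neutrophil list (3.90).

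Genes of the G1 phase and its inhibitors did not pass as groups. G1 cyclins and their kinases had 8 of 13 members lower (adjusted p = 0.0753). They passed with median-of-ratios or upper-quartile scaling (adjusted p = 0.0439 and 0.0339), without the filter on low values (0.0307) and with a filter on reads (0.0388). They also passed without calcium-low replicate 3 (0.0215) and without calcium-high replicate 4 (0.0408), 5 (0.0251) or 6 (0.0372), and in replicates 1 to 3 with median-of-ratios scaling (0.0242). Cdk6 (chromosome 5, 3341485 to 3531008) was lower, 25.3 ± 9.86 against 41.2 ± 4.36 RPKM (adjusted p = 0.0337 with the block, lower in 7 of 7 pairs), and was the member of that list that passed over all genes. Adjusted over the list alone, 3 were higher and 3 lower with the block and 0 higher, 1 lower without it. Cdk4 (46.7 ± 10.8 against 57.2 ± 6.50 RPKM), Ccnd1 (5.31 ± 1.89 against 3.75 ± 1.39), Ccnd2 (35.4 ± 8.77 against 27.6 ± 6.69), Ccnd3 (21.3 ± 7.38 against 19.5 ± 2.20), Cdc25a (3.91 ± 0.876 against 4.99 ± 0.98) and the growth regulator Myc (31.5 ± 13.5 against 43.5 ± 17.8) did not pass. Their adjusted p was 0.298, 0.124, 0.112, 0.905, 0.230 and 0.352 with the block. CDK inhibitors and pocket proteins had 11 of 17 members lower (adjusted p = 0.171), with 0 past the threshold over all genes. Adjusted over the list alone, 1 was higher and 3 lower with the block and 0 without it. Cdkn1b (p27) was at 10.5 ± 3.46 against 13.3 ± 2.77 RPKM and Cdkn1c (p57) at 3.51 ± 1.31 against 2.17 ± 1.04 RPKM, each with an adjusted p of 0.116 with the block.

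Among the calcium genes, calcium entry channels passed as a group, higher in 9 of 13 members (camera adjusted p = 0.0215; adjusted p = 0.70 with an estimated correlation). The list median lay 0.18 above that of all tested genes in replicates 1 to 3 and 0.01 below it in replicates 4 to 7. With or without the block 0 members passed over all genes and 1 was higher, 0 lower adjusted over the list alone. Trpc6, a cation channel opened by diacylglycerol, was at 11.2 ± 1.66 against 7.41 ± 0.965 RPKM (adjusted p = 0.0653 with the block, higher in 6 of 7 pairs). Cacnb2 (2.10 ± 0.467 against 1.60 ± 0.252), P2rx1_1 (7.44 ± 2.34 against 5.77 ± 1.63, a label with a copy suffix) and the store calcium sensor Stim1 (5.91 ± 0.709 against 5.40 ± 0.394) did not pass. Their adjusted p was 0.257, 0.259 and 0.622 with the block. The list's call ended without calcium-low replicate 1 (adjusted p = 0.0851), 2 (0.0603) or 3 (0.341) and without calcium-high replicate 7 (0.0508). It also ended by limma-voom (0.258), without the filter on low values (0.132), with a filter on reads (0.0581), without both libraries of replicate 3 (0.162) and in replicates 4 to 7 alone (0.537). With the block the adjusted p was 0.0479. That call ended with median-of-ratios scaling (0.0800), with voom (0.114) and without pair 1 (0.0752), 3 (0.262) or 4 (0.0552). Genes of calcium stores, pumps and exchangers did not pass (11 of 22 higher, adjusted p = 0.483), with 0 members past the threshold over all genes or adjusted over the list alone. Itpr2_1, a calcium release channel with a copy suffix, was at 1.72 ± 0.121 against 2.22 ± 0.604 RPKM and the mitochondrial exchanger Slc8b1 at 2.65 ± 0.789 against 1.99 ± 0.631 RPKM. Genes of calmodulin, its kinases, calcineurin and NFAT had 21 of 39 members higher (adjusted p = 0.0534). They passed with median-of-ratios or upper-quartile scaling (adjusted p = 0.0424 and 0.0492) and with genes detected as a covariate (0.0487). They also passed without calcium-high replicate 3 (0.0359) or 4 (0.0446) and without calcium-low replicate 5 (0.0350) or 7 (0.0489). Their 0 calls over all genes stood beside 2 higher and 0 lower adjusted over the list alone without the block and 3 higher, 1 lower with it. S100a4, a calcium-binding protein, was at 2.56 ± 0.909 against 1.07 ± 0.552 RPKM and Rcan3, a calcineurin regulator, at 2.93 ± 0.394 against 2.0 ± 0.411 RPKM.

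Nuclear genes of oxidative phosphorylation were lower, 67 of 76 members (camera adjusted p = 0.00571; adjusted p = 0.753 with an estimated correlation). They lay 0.25 below the median gene in replicates 1 to 3 and 0.03 above it in replicates 4 to 7 (adjusted p of the difference = 4.53e-04). The call ended without calcium-high replicate 1 (adjusted p = 0.0759), without calcium-low replicate 3 (0.476), without both libraries of replicate 3 (0.105), by limma-voom (0.152) and in replicates 4 to 7 alone (0.729). Ndufa5 and Cox7c, subunits of complexes I and IV, were at 1.80 ± 0.918 against 3.68 ± 2.74 RPKM and 10.8 ± 3.14 against 13.7 ± 2.91 RPKM. The 13 genes of the mitochondrial genome were listed at 0 in all 14 libraries. Ribosomal protein genes were lower, 70 of 81 (adjusted p = 0.0194; adjusted p = 0.766 with an estimated correlation). They lay 0.15 below the median gene in replicates 1 to 3 and 0.0027 below it in replicates 4 to 7 (adjusted p of the difference = 0.00288). That call ended without calcium-high replicate 1 (0.129), 2 (0.0926), 3 (0.0579) or 7 (0.0517) and without calcium-low replicate 1 (0.215), 5 (0.0555) or 6 (0.0659), in replicates 4 to 7 alone (0.821) and with genes detected as a covariate (0.188). Rpl35a was at 34.0 ± 5.28 against 40.4 ± 5.69 RPKM and Rpl23a at 410 ± 25.7 against 462 ± 58.4 RPKM. Ribosome biogenesis genes were lower, 30 of 38 (adjusted p = 0.0392; adjusted p = 0.753 with an estimated correlation). The nucleolar protein genes Ddx21 and Nolc1 were at 13.5 ± 2.33 against 16.7 ± 2.41 RPKM and at 6.79 ± 1.49 against 8.80 ± 2.20 RPKM. Its call ended without calcium-high replicate 1 (0.212), 2 (0.153), 6 (0.0518) or 7 (0.0915) and without calcium-low replicate 1 (0.0755), 3 (0.169), 4 (0.0990), 5 (0.0832) or 7 (0.0555). It also ended in replicates 1 to 3 alone (0.0567), in replicates 4 to 7 alone (0.219) and with a pseudocount of 5 (0.0501). With median-of-ratios scaling it held in replicates 4 to 7 (0.0407) and not in replicates 1 to 3 (0.151). In these 3 lists 0 members passed over all genes or adjusted over the list alone, with or without the block.

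Other metabolic and stress groups did not pass. They were genes of the tricarboxylic acid cycle (17 of 22 lower, adjusted p = 0.182), glycolysis (12 of 24 higher, 0.505), the mTORC1 pathway (12 of 25 higher, 0.451), and lysosome and autophagy (23 of 38 higher, 0.0753). The others were the unfolded protein response (22 of 29 lower, 0.367), reactive oxygen defence (14 of 24 lower, 0.584) and the interferon response (20 of 36 lower, 0.779). Each had 0 members called without the block, over all genes or adjusted over the list alone. Lysosome and autophagy genes passed with median-of-ratios or upper-quartile scaling (adjusted p = 0.0386 and 0.0339), with the block and median-of-ratios scaling (0.0439) and without calcium-high replicate 4 (0.0446). Those of the tricarboxylic acid cycle passed with genes detected as a covariate (0.0103) and without calcium-high replicate 3 (0.0370). The median log2 fold change of the glycolysis, mTORC1 and interferon lists was negative (-0.0093, -0.0020 and -0.013), while their camera statistic pointed to higher values. The mean of the mTORC1 list was positive (0.0036), and those of the glycolysis and interferon lists negative (-0.0018 and -0.0072). With the block 1 gene of the mTORC1 pathway was lower and 1 of the unfolded protein response higher, adjusted over the list alone. The latter was Trib3 (2.03 ± 0.993 against 0.964 ± 0.462 RPKM, named after its values were seen), a stress-induced pseudokinase, which also passed over all genes. Genes of p53 targets and apoptosis had 13 of 20 members lower (adjusted p = 0.0753), and passed without calcium-high replicate 3 (0.0149), without both libraries of replicate 3 (0.0219) and in replicates 4 to 7 alone (0.0429). In replicates 4 to 7 with median-of-ratios scaling the p53 list did not pass (0.0891). Among its members Bcl2l11 (BIM, a death-promoting BCL2 family member) was called lower with the block, at 1.91 ± 1.5 against 4.64 ± 1.91 RPKM, and Gadd45a was at 1.83 ± 0.755 against 2.95 ± 0.546 RPKM. Adjusted over the list alone, 0 were higher and 3 lower with the block and 2 lower without it. Cytokine receptors and signalling genes had 14 of 26 members lower (adjusted p = 0.783), and Flt3 and Il1r1 were called lower over all genes with the block. Adjusted over the list alone 3 were higher and 3 lower with it, against 0 and 2 without it. Il1r1 was at 0.703 ± 0.209 against 1.56 ± 0.318 RPKM.

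Of the marker lists of other cell types, erythroid genes passed with the block and not without it (11 of 14 higher, adjusted p = 0.0240 and 0.0644; adjusted p = 0.874 with an estimated correlation and the block). That list's mean was 3.60 in calcium-low replicate 3 and 1.82 to 2.14 in the other calcium-low libraries. Its adjusted p without that library was 7.16e-05. The list median lay 0.10 below that of all tested genes in replicates 1 to 3, with 10 of the 14 members below the median gene, and 0.29 above it in replicates 4 to 7. The list also passed without calcium-high replicate 1 (0.0203), 2 (0.0104), 4 (0.0446) or 6 (0.0372), without calcium-low replicate 6 (0.0492), by limma-voom (0.0238), with a pseudocount of 0.1 (0.0467) and in replicates 4 to 7 alone (0.00404). Aqp1, a water channel, was at 7.86 ± 4.78 against 6.55 ± 9.33 RPKM and Alas2, the erythroid enzyme of haem synthesis, at 1.23 ± 0.361 against 0.898 ± 0.314 RPKM. Neutrophil genes (9 of 11 lower, adjusted p = 0.346), monocyte, macrophage and dendritic genes (6 of 9 higher, 0.380) and endothelial genes (5 of 6 higher, 0.139) did not pass. Endothelial genes passed with a filter on reads (0.0293) and in replicates 4 to 7 alone (0.0312, or 0.0316 with median-of-ratios scaling). With the block they passed with median-of-ratios scaling (0.0194), with voom (0.0308) and without pair 1 (0.0447) or 3 (0.0393). Monocyte genes passed without the filter on low values (0.0356). Neutrophil genes passed by limma-voom with the block (0.0119) and in replicates 1 to 3 with median-of-ratios scaling (0.00239). Itgam and Csf3r were at 1.24 ± 0.757 against 2.03 ± 0.717 RPKM and 12 ± 3.45 against 17.8 ± 6.21 RPKM. The endothelial receptors Tie1 and Tek were at 31.2 ± 8.95 against 24.5 ± 3.85 RPKM and 4.26 ± 1.04 against 3.73 ± 2.11 RPKM. In these 4 lists 0 members passed over all genes with the block except Flt3, which the monocyte list also held. Adjusted over the list alone the block gave 0 higher and 1 lower for erythroid, 0 and 2 for neutrophil, 1 and 1 for monocyte, and 0 and 0 for endothelial genes. Without the block these were 0 apart from 1 lower for monocyte genes.

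**Figure D3:**
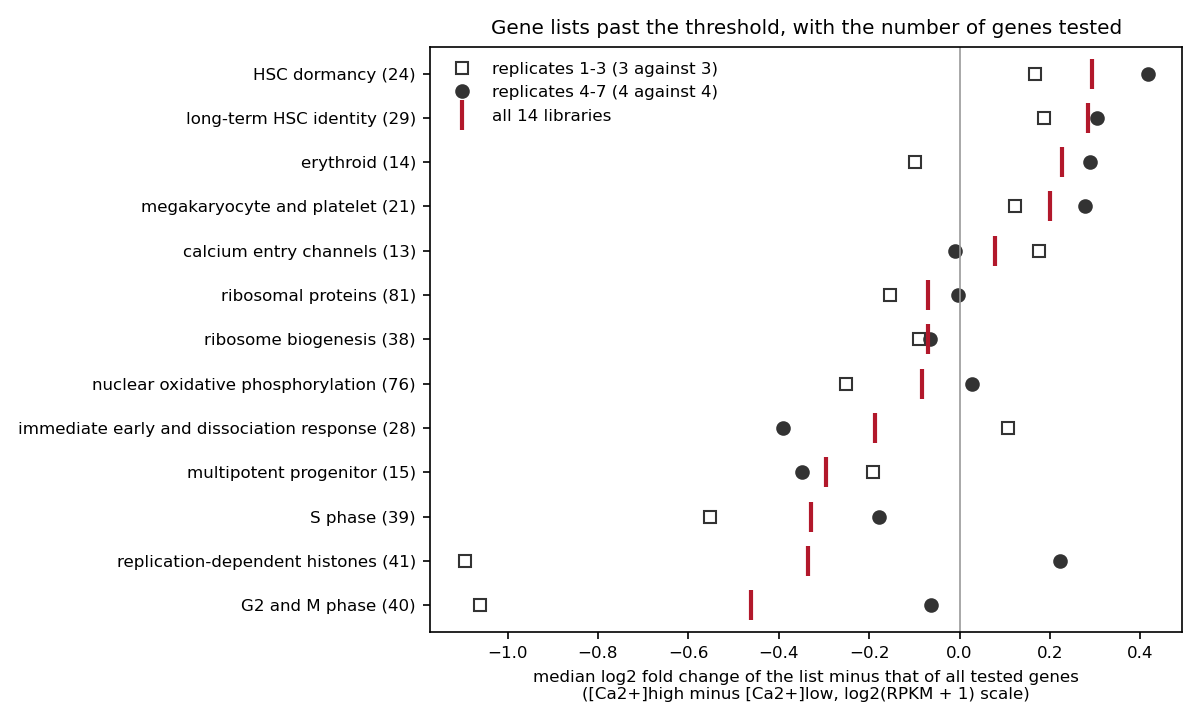
Median log2 fold change of each list minus that of all tested genes (horizontal axis, log2(RPKM + 1) scale, calcium-high minus calcium-low) for the lists past the threshold in either fit (vertical axis, number of tested genes in brackets), with open squares for replicates 1 to 3, filled circles for replicates 4 to 7 and bars for all 14 libraries. The immediate early list lay 0.11 above the median gene in replicates 1 to 3 and 0.39 below it in replicates 4 to 7.

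In all, camera called 4 lists higher and 8 lower among 29 without the block, and 5 higher and 8 lower with it. With a correlation estimated for each list it called 0 in either fit, where 0.246 was the adjusted p of the HSC identity list without the block and 0.696 with it. The other planned list test, fry of limma, called no list in a single direction. Its smallest adjusted p was 0.0593 without the block and 0.156 with it, both for immediate early genes. For S phase and HSC identity it was 0.250 without the block. Its form that allows either direction passed for dormancy and for megakaryocyte and platelet genes (0.00838 each) without the block, and for more lists with it. Exchanging the group labels within pairs gave at least 13 lists by camera in 5 of 64 arrangements. In single pairs the list mean, with no correction for the shift of the median gene, often went against the direction of the list. For lists called higher this was pair 3 for HSC identity and for dormancy, pairs 1 and 3 for megakaryocyte and platelet, 1 and 2 for calcium entry channels, and 1, 2 and 3 for erythroid genes. For lists called lower it was pair 5 for S phase, pairs 5 and 6 for G2 and M phase, oxidative phosphorylation and ribosome biogenesis, 4, 5 and 6 for ribosomal proteins, 4 and 5 for histones, 5 and 7 for multipotent progenitors, and 0 of 7 pairs for immediate early genes.

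The library sets, replicates 1 to 3 and 4 to 7, differed in what they held. The median gene had a log2 fold change of -0.20 in replicates 1 to 3 and 0.11 in replicates 4 to 7, and the medians above are given relative to these. Replicates 4 to 7 alone gave 631 genes higher and 177 lower by limma, and 253 higher and 356 lower with median-of-ratios scaling. The share of higher calls was 78.1% and 41.5%. Replicates 1 to 3 alone gave 0 calls by limma, with 1151 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.421, and 0 with median-of-ratios scaling. Relative to the median gene, 82.6% of the 808 genes called in replicates 4 to 7 had the same direction in pair 1, 79.8% in pair 2 and 55.9% in pair 3. The test of a difference between the sets called 0 genes by limma, with 2841 at an unadjusted p under 0.05. Across genes, which are not independent replicates, the fold changes of the sets had a Spearman correlation of 0.247, and 3 of 100 permutations of the group labels gave one as large. That count took only permuted correlations at or above the observed value. The two-sided limits of the permuted correlations, with the extremes left out, were -0.266 and 0.253, and 0.247 lay within them.

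Libraries of calcium-high HSCs had 14923 ± 247 genes detected and those of calcium-low HSCs 14691 ± 219 (n = 7), a difference of 232 (exact two-sided permutation p = 0.0857 over 3432 assignments, 0.257 adjusted over 3 measures). After thinning each library to the depth of the smallest the difference was 277 (exact permutation p = 0.0332, unadjusted). Within replicates 4 to 7 the difference was 411 before thinning and 398 after it (exact permutation p = 0.0286 for each, the smallest that 4 against 4 can give). Within replicates 1 to 3 it was -7 before thinning and 117 after it (exact permutation p = 0.5 after thinning), where 3 against 3 cannot go below 0.1. Reads in listed genes (7.47 ± 2.79 against 7.79 ± 2.41 M reads, exact permutation p = 0.830) and the share of reads in the top 10 genes (5.32% ± 0.758 against 5.57% ± 0.898, exact permutation p = 0.573) did not differ by this test. The share of the authors' library total in listed genes went in opposite directions in the library sets. Calcium-high minus calcium-low, it was -5.12 percentage points in replicates 1 to 3 (exact permutation p = 0.1). In replicates 4 to 7 it was 1.87 (exact permutation p = 0.0286). RPKM does not correct for this share, and the median log2 fold change had the same signs (-0.20 and 0.11). With median-of-ratios scaling that median was 0.0014 and -0.00059.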

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

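The tests chosen only after the result was seen were the residual variance with and without the block, the 2 tests of replicate 3 on the S phase and G2 and M phase lists, the share of neutrophil genes highest in calcium-low replicate 3, and the comparison of depth within replicates 4 to 7. The other tests below were written before their results were seen.

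In 35 of 244 groups of 7 values, for named genes, lists and library measures, the highest or lowest library stood far from the other 6, where chance gives about 1 in 20, or 12.2. Calcium-high replicate 3 accounted for 15 of the 35, calcium-low replicate 3 for 14, calcium-low replicate 1 for 3, and calcium-low replicates 2 and 5 and calcium-high replicate 5 for 1 each. In calcium-high replicate 3 the highest values were Dnajc6 at 4.30 RPKM (1.77 to 2.40 in the other calcium-high libraries), Cd69 at 3.38 (0.195 to 1.2), Rgs1 at 62.7 (9.66 to 23.9), Rel at 4.23 (1.98 to 2.70), Tnfaip3 at 8.80 (2.61 to 5.26), Cdk6 at 46.5 (16.6 to 25.8), Aqp1 at 17.8 (3.47 to 9.06) and Bcl2l11 at 5.20 (0.756 to 1.85). Its lowest values were Evc2 at 0.977 RPKM (2.95 to 4.28), Tbxas1 at 16.3 (24.8 to 30.9) and Procr at 2.37 (7.32 to 10.7). Its list means were lowest for HSC identity at 3.37 log2(RPKM + 1) (3.77 to 4.01), HSC dormancy at 2.76 (3.16 to 3.34), the interferon response at 2.87 (3.27 to 3.45) and endothelial genes at 3.11 (3.47 to 3.73).

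In calcium-low replicate 3 the highest values were 15142 genes detected (14491 to 14757 in the other calcium-low libraries), Tnfaip3 at 13.9 RPKM (5.63 to 7.84), Mki67 at 69.0 (0.911 to 5.27), Dlgap5 at 7.39 (0.627 to 2.40), Smc4 at 16.3 (2.90 to 8.48), Ect2 at 12.4 (0.701 to 1.81), Hist1h4c at 24.1 (4.49 to 12.5) and Aqp1 at 27.7 (2.49 to 3.85), and Ccnd2 was lowest at 13.4 (26.5 to 33.5). Its list means were highest for G2 and M phase at 4.37 log2(RPKM + 1) (1.51 to 2.0), erythroid at 3.60 (1.82 to 2.14), neutrophil at 3.90 (0.966 to 1.48) and histone genes at 4.28 (1.32 to 2.59), and lowest for calcium entry channels at 2.14 (2.33 to 2.47). Calcium-low replicate 1 was highest in Ndufa5 at 9.35 RPKM (1.5 to 4.72), Rpl23a at 594 (431 to 447) and the ribosomal protein list at 7.68 (7.11 to 7.28). Calcium-low replicate 2 was highest in Alas2 at 1.56 RPKM (0.655 to 0.952), calcium-low replicate 5 in Btg2 at 47.8 RPKM (20.3 to 29.9), and calcium-high replicate 5 in the histone list at 2.99 (1.13 to 1.70).

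Camera on the interaction term of limma, at the preset correlation of 0.01, called a difference between replicates 1 to 3 and 4 to 7 for 9 lists. No estimated correlation was tried for this term, and with one the group calls of all lists had ended. For single genes limma called 0 on this term. The camera adjusted p was 1.81e-15 for immediate early genes, 4.53e-04 for multipotent progenitor genes and for oxidative phosphorylation, 0.00276 for S phase, 0.00288 for ribosomal proteins, 0.0141 for cytokine receptors and signalling, 0.0156 for G2 and M phase, 0.0169 for histones and 0.0395 for the interferon response.

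Other arrangements of the group labels were fitted in the same way. Without the block, of 100 drawn splits of the 14 libraries 17 gave at least the 669 genes of the real split at an unadjusted p under 0.05 (highest other 4365) and 16 at least its 12 lists (highest other 15), so chance cannot be excluded for these. The count of 0 genes past the threshold is reached by any split, all 100 here, so the splits decide nothing about it. The highest count, 2984 genes, came from a split that put replicates 1 to 3 of both groups and calcium-low replicate 5 on one side, which points to a structure of the libraries along the sets; with the set as a term, 51 genes passed. Exchanging labels within pairs gave at least the real 91 genes in 2 of 64 arrangements, all of which part all 7 pairs. Chance is unlikely at that share and is not excluded. The other arrangement gave 92 genes by exchanging replicate 3, and the next gave 2. For the 13 lists with the block chance cannot be excluded either, since 5 of 64 gave as many (highest other 14). In replicates 4 to 7 the real split alone of 35 gave as many as 808 genes (highest other 1), the smallest share that 35 splits can give. Chance is unlikely there and is not excluded, since these shares were not adjusted for the number of such tests. In replicates 1 to 3 the 10 splits are too few for a share under 0.05, and all 10 gave 0 genes.

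The first pattern was that 0 genes passed without the pairing and 91 with it. The tables argue against calls resting on replicate 3, since 302 genes passed with the block when both its libraries were left out. Variation shared by libraries of the same number may account for the pattern, as the block brought the median residual variance to 0.592 of that without it, and the library set alone to 0.711. An exchange of the group labels in replicate 3 stays open: 55.9% of the 808 genes called in replicates 4 to 7 had their direction in that pair, against 82.6% and 79.8% in pairs 1 and 2. The calcium level itself stays among the open explanations of the 91 calls.

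The second pattern was the lower level of S phase and of G2 and M phase genes in calcium-high HSCs. For S phase genes the tables argue against calcium-low replicate 3 as the whole source of the call at the preset correlation. That call held without both libraries of replicate 3 (camera adjusted p = 3.31e-09). In replicates 4 to 7, 34 of the 39 members lay below the median gene. For G2 and M phase genes that library cannot be told apart from the group. At the preset correlation the call ended without it (camera adjusted p = 0.0608) and held without the pair (camera adjusted p = 0.0171). With an estimated correlation neither list passed with all libraries (camera adjusted p = 0.387 and 0.717). These fits therefore do not decide whether either list differs between the groups beyond chance. Whether cells of other lineages in calcium-low replicate 3 were a source of the signal stayed undecided. In that library 2 of 4 mature lineage lists had their highest calcium-low mean, and S100a8 and S100a9 were at 392 and 223 RPKM. Of the tested neutrophil genes, 45.5% had their highest of 14 values there. That share is partly set by the filter on mean RPKM, which S100a9 and Ngp passed only through this library (at most 0.959 and 0.216 RPKM elsewhere). Of the 21 neutrophil genes in the list, 11 were tested. These markers do not show whether such cells held the cell cycle transcripts. Of the 14 erythroid and 11 neutrophil genes tested 3 and 5 are also in another list. The labels name the sorted cells as HSCs and give no other gate, so what the sort removed is not known.

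The third pattern was the lower level of immediate early genes in calcium-high HSCs in replicates 4 to 7. A difference in depth is argued against by a ratio of mean reads, calcium-high over calcium-low, of 1.0 in these libraries. Heat or dissociation stress in the calcium-low libraries may be a source, since the heat shock list tested lower in calcium-high HSCs in these replicates (limma camera adjusted p = 0.0403). That list was lower only relative to other genes. Its median log2 fold change was 0.05, with 7 of its 16 genes lower, and lay 0.06 below that of all tested genes, with 13 genes below the median gene, against 0.39 below for the immediate early list. None of its genes passed alone in replicates 4 to 7 (smallest limma adjusted p = 0.128, Hspa4). The calcium level, and handling that differed between the library sets, stay open and were not tested further.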

How the results depend on the processing

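The settings chosen only after the data were seen were the block with median-of-ratios scaling, voom, an estimated correlation or 1 pair left out, each library set with median-of-ratios scaling, and both libraries of replicate 3 left out. The planned edgeR, DESeq2 and svaseq fits were not run, because the design set limma for files in RPKM. The recovered reads would have allowed fits on counts, and of these only limma-voom was run. Of the settings of the 87 tested named genes 2770 kept direction and side of the threshold, 515 now passed and 17 reversed; of those of the 29 lists these were 967, 53 and 54, and 85 no longer passed. The cause of these changes was not tested, except that fewer libraries were fitted where some were left out. Apart from the genes it brought past the threshold and the erythroid list, the block changed no call. Depth limits low genes: 3 reads in a gene of 1 kilobase are 0.0808 to 0.210 RPKM.

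Genes higher and lower, 0 and 0 without the block, were 4 higher with median-of-ratios scaling, 3 higher with upper-quartile scaling, 1 higher without the filter, 3 and 3 with the CPM filter, 465 and 249 by voom, 48 and 43 with the block, 22 and 29 with the library set as a term, and 631 and 177 in replicates 4 to 7 (253 and 356 with median-of-ratios scaling). Without both libraries of replicate 3 they were 78 and 41, and 164 and 138 with the block. The block gave 216 and 72 with median-of-ratios scaling, 578 and 277 with voom, 5 and 3 without pair 1, 1 and 2 without pair 2, 2 and 10 without pair 5, and 0 and 2 without pair 6. With genes detected as a covariate, pseudocounts of 0.1 or 5, or replicates 1 to 3 alone they stayed at 0 by limma, with 845, 651, 667 and 1151 genes at an unadjusted p under 0.05. Leaving out each library gave 0 to 69 higher, the highest without calcium-high replicate 3, and 0 to 32 lower; calls also came without calcium-low replicate 1 (2 higher), 2 (3 and 2) and 3 (7 and 13).

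Lists higher and lower, 4 and 8, were 0 and 0 with an estimated correlation, with or without the block; lists lower were 5 in replicates 1 to 3, 4 in replicates 4 to 7 with either scaling, and 5 with the block without pair 1. Leaving out each library gave 3 to 7 higher and 5 to 9 lower. Thinning brought the difference in genes detected, 232, to 277 and under the threshold, counting genes with 5 reads to 190. The correlation of fold changes between sets, 0.247, was 0.273 for genes of 20 CPM or more.

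In replicates 4 to 7 alone, lists that reversed were oxidative phosphorylation (adjusted p = 0.729; 0.886 with median-of-ratios scaling), the tricarboxylic acid cycle (0.729), glycolysis (0.821; 0.514), the interferon response (0.729; 0.817) and reactive oxygen defence (0.709; 0.843), and with that scaling only neutrophil (0.733) and histone genes (0.171). In replicates 1 to 3 these were immediate early genes (0.0838; 0.163), cytokine receptors (0.123; 0.136), monocyte genes (0.599; 0.0890) and, with that scaling, erythroid genes (0.698). Without both libraries of replicate 3 these were glycolysis (0.821; 0.778 with the block), reactive oxygen defence (0.920; 0.929) and neutrophil genes (0.899; 0.951). Glycolysis reversed by voom (0.477; 0.814 with the block) and the interferon response without the filter (0.599) and with the block without pair 2 (0.474) or 7 (0.962). Cytokine receptors reversed with the block (0.979; 0.682 with median-of-ratios scaling; 0.990 with an estimated correlation), with genes detected as a covariate (0.694), and with the block without pair 2 (0.856), 4 (0.711), 5 (0.715), 6 (0.816) or 7 (0.974). Over the fits that left out 1 library each, where these lists reversed in some, the adjusted p ran from 0.0370 to 0.793 for the tricarboxylic acid cycle, 0.272 to 0.958 for glycolysis, 0.231 to 0.940 for the interferon response, 0.219 to 0.959 for reactive oxygen defence, 0.211 to 0.929 for cytokine receptors and 0.0873 to 0.725 for neutrophil genes.

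Genes that reversed in replicates 1 to 3, with the log2 fold change there, were Hlf (-0.035), Ccnd3 (-0.36; -0.12 with median-of-ratios scaling), Stim1 (-0.021), Btg2 (0.0038; 0.25), Aqp1 (-0.053), Tek (-0.12) and, with that scaling, Rpl35a (0.14) and Itpr2_1 (0.073), and in replicates 4 to 7 Mki67 (0.27; 0.18). Ccnd3 also reversed with genes detected as a covariate (-0.00092) and with the block without pair 5 (-0.025) or 6 (-0.040), and ran from -0.049 to 0.16 over the fits that left out 1 library.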

Other observations

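The genes and the list described here were chosen only after the values were seen, and the tests of the list too.

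The chemokine gene Ccl4 was at 5.58 ± 1.49 in calcium-high and 19.5 ± 10.8 RPKM in calcium-low libraries (SD, n = 7; limma adjusted p = 0.0337 with the block). Ccl3, another chemokine gene, was at 1.03 ± 0.907 against 9.57 ± 8.22 RPKM (limma adjusted p = 0.0610 with the block and 2.30e-04 in replicates 4 to 7 alone).

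A list of 16 NF-kB and activation genes that holds both was tested by camera of limma. It was lower in calcium-high HSCs without the block (adjusted p = 8.53e-05), with it (2.40e-04) and in replicates 4 to 7 (2.68e-07), and did not pass in replicates 1 to 3 (0.806). These values are no evidence for a group difference, since the list was made after the values were seen and holds Rel, Cd69, Rgs1 and Tnfaip3, which had been called lower already. No estimated correlation was tried for it.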
